A study of Mus musculus with 8 samples.

How the data were processed

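Bulk RNA sequencing of colon was analysed from germ-free C57BL/6 female mice, 6 weeks old and kept in gnotobiotic isolators. Mice were given C. albicans SC5314 (3 libraries) or C. tropicalis MYA-3404 (2 libraries) by mouth, or served as controls (3 libraries), and colon was taken at day 30. The labels number the replicates of each group and do not say whether each library is a separate mouse, so p-values measure the spread between these 8 libraries, which may be technical in part. Isolator, cage and handling session were not part of the comparisons, so their effects are not separated from group. Libraries were made with the NEBNext Ultra RNA kit, which does not keep the strand, so reads of overlapping genes on opposite strands cannot be separated.

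One deposited table holds counts, as whole numbers of reads for 52636 Ensembl gene identifiers in each of the 8 libraries, with no normalization. The submitters' processing notes name TopHat2 2.0.12, HTSeq (version written as 6.1), DESeq 1.18.0 and the mouse build mm10. The annotation release, strand setting and filters are not given in the sources used here. Symbols and positions were taken from GENCODE M21 on the same build. In that annotation 52489 identifiers were found, and the other 147 held 0.00317% of all counts. Total counts ran from 16195376 to 19761098 per library, and the 10 most abundant genes took 6.22% to 6.96% of them. A count of 0 allows up to 3 counts, or 0.152 to 0.185 CPM (counts-per-million) depending on the library; this floor covers counting error only. No pair of libraries within a group had counts that differed by as little as sampling noise, so all 8 were kept.

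Genes were tested with edgeR 4.0.16 in R 4.3.3 using TMM normalization, its default filter on low counts (filterByExpr on the 3 groups) and the quasi-likelihood F-test. One fit of the 8 libraries gave the contrasts C. albicans against control, C. tropicalis against control and C. tropicalis against C. albicans, with 16107 genes tested and 36529 not. The fit had 5 residual degrees of freedom, a prior of 4.05 degrees of freedom and a common biological coefficient of variation of 0.243. P-values were adjusted by Benjamini-Hochberg within each contrast, with 0.05 as the threshold and no minimum fold change. Levels are CPM with TMM-adjusted library sizes, as mean ± SD. Log2 fold changes carry a standard error (SE) obtained as their size divided by the square root of F.

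Gene lists for pathways and cell types, 41 in number, were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, an inter-gene correlation preset at 0.01 and adjustment over the lists of each contrast. Lists needed 5 tested members, which left 40; the pancreatic acinar list, with 2, was not tested. Camera was repeated with an estimated correlation, and fry was run beside it. A list's score in a library is the mean log2 CPM of its members minus the mean over the 8 libraries. Bootstrap intervals of medians resample genes and not libraries, so they do not measure the spread between libraries.

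The lists, the comparisons, the tests and the rule for naming genes were fixed before the data were examined. By that rule a contrast names up to 10 genes past the threshold in each direction, where the groups do not overlap and the mean CPM is at least 1. Where under 5 genes passed, the 10 with the smallest p are named as not passing. The rule adds up to 4 members of each list past the threshold, or for a list past the threshold with none, the 2 members with the smallest p. It also adds 14 readouts of antifungal and barrier defence chosen beforehand, whatever their values. A few of the genes it names are not reported here; they stay in the tests and lists. Predicted genes, Rik names, immunoglobulin and T cell receptor segments and pseudogenes were left out of the ranking.

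Alternatives covered DESeq2 1.42.0 as a test and as a source of size factors, upper-quartile factors, limma-voom, no filter and a stricter one (CPM of at least 1 in 3 libraries), a fit of only the 2 groups compared, the replicate number as a block, a minimum fold of 1.5, a threshold of 0.1, and each library left out in turn. Where this leaves 1 C. tropicalis library, it is assumed to vary like the other groups. The minimum fold was set inside the test (glmTreat), which asks whether a fold lies beyond 1.5. A gene with an estimate above 1.5 can therefore miss. A smooth muscle score as a covariate, a correction for GC content and, for the correlation of the colonization contrasts, a split of the controls between them were added after the data had been seen. The correlation of the 2 colonization contrasts was set beside 100 simulated data sets with no response to either species and the same controls. The fit was also tested on simulated data with known changes: it recovered 36% of 2-fold and 82% of 4-fold changes for C. albicans, and 25% and 76% for C. tropicalis, calling 5 and 8 of 15907 unchanged genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.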

Results

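Colon of germ-free mice colonized for 30 days with C. albicans (n = 3 libraries) or C. tropicalis (n = 2) was compared with colon of control mice (n = 3). The libraries held 16195376 to 19761098 counts, and 16107 genes were tested. The first principal component, with 48.7% of the variance, separated the species, with C. tropicalis 1 and 2 at 53.6 and 46.4 and C. albicans 1, 2 and 3 at -3.19, -67.0 and -43.2, while control 1, control 2 and control 3 were spread along it at -39.9, 10.0 and 43.3. Control 3 thus lay close to the C. tropicalis libraries. The smooth muscle score fell along this component, also within the controls (0.53, 0.07 and -0.52 in control 1, 2 and 3), so it is not an axis of the species alone.

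With C. albicans, genes of the circadian clock differed from control in both directions. The labels give no hour of collection, so an effect of colonization cannot be told apart from collection at another time. Arntl, which encodes the clock activator BMAL1, fell from 42.2 ± 5.50 to 13.1 ± 0.881 CPM (SD, n = 3 and 3), a log2 fold change of -1.69 ± 0.14 (SE, adjusted p = 0.00941). The clock repressors rose: Per2 from 35.2 ± 5.22 to 149.6 ± 22.3 CPM (4.25-fold, log2 2.09 ± 0.20, adjusted p = 0.0150), Per1 from 91.8 ± 4.24 to 228 ± 22.0 CPM (2.48-fold, log2 1.31 ± 0.14, adjusted p = 0.0222), and Ciart, which opposes BMAL1, from 4.995 ± 1.82 to 29.3 ± 2.05 CPM (5.88-fold, log2 2.56 ± 0.26, adjusted p = 0.0158). The heat shock chaperone gene Hsph1 rose from 32.7 ± 5.03 to 182 ± 56.7 CPM (5.57-fold, log2 2.48 ± 0.28, adjusted p = 0.0227). C2cd4a, which encodes a nuclear protein with a C2 domain, rose from 5.87 ± 1.53 to 48.9 ± 13.2 CPM (8.35-fold, log2 3.06 ± 0.30, adjusted p = 0.0150), and Rbm14, an RNA-binding paraspeckle component, rose from 19.2 ± 1.19 to 43.6 ± 6.05 CPM (2.27-fold, log2 1.1801 ± 0.13, adjusted p = 0.0227). For each of these genes, every C. albicans library lay on the same side of all 3 controls, which the rule for naming them requires. Over all tested genes 19.4% did so, where chance gives 10%.

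Those 7 genes, 6 higher and 1 lower, were all that passed in the edgeR test, which gave 2487 genes at an unadjusted p under 0.05 where chance gives 805, and 43 at an adjusted p under 0.1. The count was 461 with DESeq2, 119 with no filter on low counts, 4 after correction for GC content (C2cd4a, Per1 and Rbm14 were lost) and 0 with the replicate number as a block; without 1 library it was 1 (control 1), 1 (control 2), 2 (control 3), 254 (C. albicans 1) and 0 (C. albicans 3), and Rbm14 also missed without C. albicans 2 (adjusted p = 0.135), C. tropicalis 1 (0.0753) or C. tropicalis 2 (0.0749), with only the 2 groups (0.0754) and with a smooth muscle score as a covariate (0.0525). Tested against a minimum fold of 1.5, 4 genes passed, without Hsph1 (adjusted p = 0.0587), Per1 (0.169) and Rbm14 (0.242). On GRCm38 the 7 genes lie as follows. Arntl (ENSMUSG00000055116) spans chromosome 7 from 113207465 to 113314126, and Per2 (ENSMUSG00000055866) chromosome 1 from 91415982 to 91459324. Per1 (ENSMUSG00000020893) spans chromosome 11 from 69095217 to 69109960, and Ciart (ENSMUSG00000038550) chromosome 3 from 95878503 to 95882251, a stretch also covered on the other strand by C920021L13Rik (96 counts over the 8 libraries, against 2260 for Ciart). Hsph1 (ENSMUSG00000029657) lies on chromosome 5 from 149614287 to 149636376, C2cd4a (ENSMUSG00000047990) on chromosome 9 from 67830489 to 67832330, and Rbm14 (ENSMUSG00000006456) on chromosome 19 from 4800569 to 4811634, overlapped on its own strand by Gm21992 (107 counts, against 5130).

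**Figure D1:**
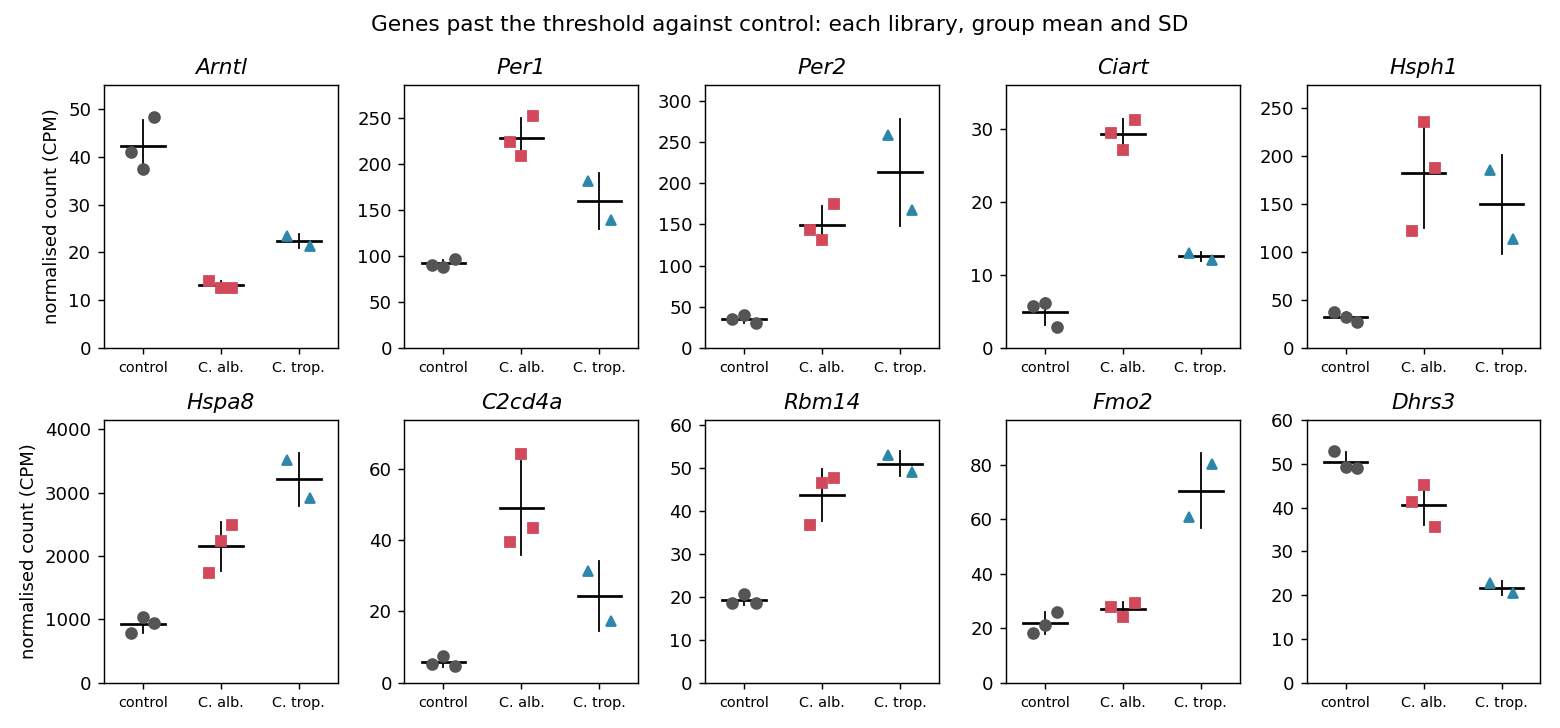
Normalised read count in CPM (y axis, linear from 0) of the 10 genes past the threshold in either colonization contrast, one point per library, with the group mean (bar) and SD (line) for control, C. albicans and C. tropicalis. Arntl and Dhrs3 lie below control in both colonized groups and the other 8 genes above it, though not every gene passed the test in both.

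The clock list held 19 tested genes, of which 15 lay above control and 4 below with C. albicans. Over all genes 4 passed, and 13 passed adjusted over the list alone, 10 higher and 3 lower. The list as a whole was higher by camera (median log2 fold change 0.71, adjusted p = 9.26e-05; adjusted p = 0.476 with an estimated correlation; adjusted p = 0.0215 by fry). Among clock genes chosen after their values were seen, Dbp had a log2 fold change of 2.004 ± 0.31 (adjusted p = 0.0711) and Npas2, a partner of BMAL1, -1.25 ± 0.20 (adjusted p = 0.0776). The list of immediate early and heat shock genes was also higher (median 0.68, 21 of 24 members above control, adjusted p = 5.0e-09; adjusted p = 0.476 with an estimated correlation; adjusted p = 0.0470 by fry). In it 1 gene passed over all genes and 12 adjusted over the list alone, all of them higher. The unfolded protein response list was higher (median 0.22, 23 of 26 above control, adjusted p = 0.000503; adjusted p = 0.794 with an estimated correlation and 0.319 by fry), with no member past the threshold over all genes and 4 adjusted over the list alone. Its members with the smallest p were Hspa5, the main chaperone of the endoplasmic reticulum (log2 1.004 ± 0.17, adjusted p = 0.0929), and Creld2 (1.14 ± 0.23, adjusted p = 0.133). These 3 lists kept their call without each of the 8 libraries in turn, with adjusted p no higher than 0.000899 for the clock, 1.63e-05 for heat shock and 0.0259 for the unfolded protein response.

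**Figure D2:**
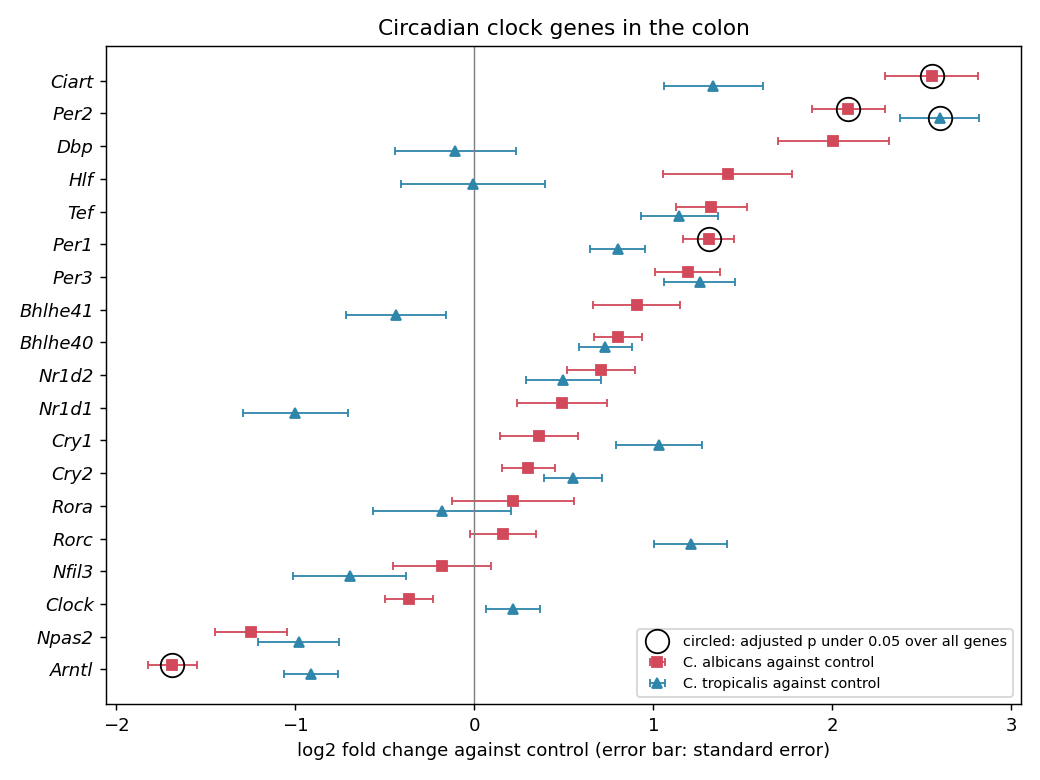
Log2 fold change against control (x axis, with standard error) of the 19 tested clock genes (y axis) for C. albicans (squares) and C. tropicalis (triangles), circled where the adjusted p over all genes is under 0.05. Per2 lies at 2.09 and 2.599 in the 2 contrasts and Arntl at -1.69 and -0.91, while Dbp lies at 2.004 with C. albicans and at -0.11 with C. tropicalis.

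Genes of cholesterol synthesis were lower with C. albicans in 23 of 24 cases (median -0.30, adjusted p = 0.000571; adjusted p = 0.794 with an estimated correlation; 2 lower adjusted over the list alone, 0 over all genes). Insig1, a sensor of sterol levels, had a log2 fold change of -0.89 ± 0.19 (adjusted p = 0.150) and Fdps, an enzyme of isoprenoid synthesis, -1.11 ± 0.26 (adjusted p = 0.165). Without control 2 the list no longer passed (adjusted p = 0.119). Markers of small intestine or caecum were lower in 9 of 12 cases (median -0.70, adjusted p = 0.0161; adjusted p = 0.476 with an estimated correlation; 2 adjusted over the list alone, 0 over all genes), with Rbp2 at -1.01 ± 0.21 (adjusted p = 0.144). Leaving out control 1 ended that call (adjusted p = 0.117). Hypoxia and glycolysis genes were higher (median 0.17, 22 of 31, adjusted p = 0.0150; adjusted p = 0.794 with an estimated correlation; 4 higher and 1 lower adjusted over the list alone, 0 over all genes), with P4ha1 at 0.88 ± 0.18 (adjusted p = 0.128) and Hif1a at 0.52 ± 0.11 (adjusted p = 0.150). That call ended without control 1 (adjusted p = 0.183), control 3 (0.0904) or C. albicans 3 (0.137). The hypoxia median was 0.34 without control 2 and 0.30 without C. albicans 1, and the cholesterol median -0.11 without control 2 and -0.20 without C. albicans 2. With the smooth muscle score as a covariate, chosen after the data had been seen, the small intestine or caecum median was -0.46 and the hypoxia median 0.26, both still past the threshold.

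Muscle and nerve markers were higher with C. albicans: 22 of 22 smooth muscle genes (median 0.66, adjusted p = 0.00046) and 22 of 23 genes of enteric neurons and glia (median 0.52, adjusted p = 0.00127), each with adjusted p = 0.794 with an estimated correlation. No member of either list passed over all genes, and adjusted over the list alone 0 muscle genes and 1 nerve gene did. Actg2, the smooth muscle actin of the gut, stood at 3931 ± 2307 CPM against 1915 ± 497 (log2 1.04 ± 0.39, adjusted p = 0.278), Hspb6 at 1.02 ± 0.37 (adjusted p = 0.271), Foxd3 at 1.30 ± 0.29 (adjusted p = 0.151) and Ret, a receptor of enteric neurons, at 0.75 ± 0.24 (adjusted p = 0.248). Without control 3 both calls ended (adjusted p = 0.0581 for each), as they did without C. albicans 2 (0.0820 for muscle, 0.101 for nerve). The muscle median ran from 0.26 (without C. albicans 2) and 0.41 (without control 3) to 1.008 (without control 1), and that of nerve from 0.19 (without C. albicans 2) to 0.78 (without C. albicans 1). With the smooth muscle score as a covariate the nerve median was 0.0549 and its call ended (adjusted p = 0.663). The smooth muscle score was 0.02 ± 0.53 in controls and 0.65 ± 0.71 with C. albicans (SD, n = 3 and 3).

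Lower with C. albicans were 19 of 20 genes of B cells and follicles (median -1.80, adjusted p = 0.00542) and 12 of 13 of MHC class II presentation (median -0.62, adjusted p = 0.0150), each with adjusted p = 0.794 with an estimated correlation. Plasma cell and immunoglobulin genes (median 0.33, adjusted p = 0.127) and genes of T cells and innate lymphoid cells (median -0.54, adjusted p = 0.160) did not pass as lists. Over all genes 0 passed in both lists, and adjusted over the list alone 1 B cell gene passed (Blnk, higher) and 0 MHC genes. The B cell regulator Pax5 had a log2 fold change of -2.63 ± 0.91 (adjusted p = 0.263), Blnk, the exception to the list's direction, 0.62 ± 0.14 (adjusted p = 0.151), H2-Ob -1.996 ± 0.76 (adjusted p = 0.282) and H2-Eb2 -1.79 ± 0.81 (adjusted p = 0.329). The B cell scores of the controls ranged from -1.52 to 1.79. Both calls ended without control 2 (adjusted p = 0.0663 for B cells, 0.109 for MHC class II), control 3 (0.222 and 0.241) or C. albicans 2 (0.155 and 0.170), and the MHC median was -0.94 without control 1 and -0.39 without control 3. They also ended with the smooth muscle score as a covariate, where the medians were -0.46 (adjusted p = 0.932) and -0.18 (0.860) and the direction of both tests turned; within groups the smooth muscle score ran against those of B cells (r = -0.839 over 8 libraries) and MHC class II (r = -0.843).

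Cell cycle genes were lower in 29 of 32 cases (median -0.32, adjusted p = 0.0113; adjusted p = 0.810 with an estimated correlation), with Rrm1 at -0.43 ± 0.19 (adjusted p = 0.316) and Mcm7 at -0.32 ± 0.16 (adjusted p = 0.356), and the call ended without control 1 (adjusted p = 0.823) or C. albicans 2 (0.271). Tuft cell genes were higher (median 0.35, 17 of 20, adjusted p = 0.0150; adjusted p = 0.794 with an estimated correlation), with Ptgs1 at 1.03 ± 0.40 (adjusted p = 0.284) and Hpgds in the other direction at -0.71 ± 0.23 (adjusted p = 0.247); the call ended without control 3 (adjusted p = 0.451) or C. albicans 3 (0.114). Fibroblast genes were higher (median 0.26, adjusted p = 0.0393; adjusted p = 0.810 with an estimated correlation), with Fn1 at 0.83 ± 0.22 (adjusted p = 0.203) and Col5a1 at 0.80 ± 0.22 (adjusted p = 0.206). That call ended without control 1 (adjusted p = 0.112), control 2 (0.181), C. albicans 2 (0.701) or C. tropicalis 1 (0.0502). Endothelial genes were higher (median 0.18, adjusted p = 0.0496; adjusted p = 0.794 with an estimated correlation), with Eng at 0.81 ± 0.21 (adjusted p = 0.201) and Vwf at 0.55 ± 0.16 (adjusted p = 0.231). Their call ended without control 1 (adjusted p = 0.368), control 2 (0.0563), C. albicans 2 (0.142), C. albicans 3 (0.131) or C. tropicalis 1 (0.0502). Leaving out 1 library put the cell cycle median at -0.000081 (control 1), -0.53 (control 3) or -0.54 (C. albicans 1), that of tuft cells at 0.67 (control 1), 0.54 (control 2) or 0.16 (control 3), that of fibroblasts at 0.0026 (C. albicans 2) or 0.41 (C. albicans 3) and that of endothelium at 0.33 (C. albicans 1). The calls of tuft cell (median 0.24, adjusted p = 0.189), fibroblast (0.0771, adjusted p = 0.450) and endothelial genes (0.0958, adjusted p = 0.121) ended with the smooth muscle score as a covariate. In all 4 of these lists 0 members passed, over all genes or adjusted over the list alone. Altogether 14 of 40 lists passed by camera, 9 higher and 5 lower, 2 by fry and 0 with an estimated correlation, where 3 had an unadjusted p under 0.05.

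None of the tested readouts of antifungal and barrier defence passed with C. albicans. The smallest p among them was that of Duox2, an epithelial enzyme that makes hydrogen peroxide, at 165 ± 66.3 CPM against 53.9 ± 10.2 (SD, n = 3 and 3; log2 1.61 ± 0.27, adjusted p = 0.0929). Muc2, the main mucin of the colon, stood at 5107 ± 1167 CPM against 3044 ± 1080 (log2 0.75 ± 0.27, adjusted p = 0.265), and Retnlb, a goblet cell product, at 15.4 ± 12.6 against 2.22 ± 2.85 (2.79 ± 1.17, adjusted p = 0.309). The log2 fold changes were 1.20 ± 0.63 for Reg3g, 0.19 ± 0.38 for Lcn2, -0.69 ± 0.33 for Clec7a (the beta-glucan receptor dectin-1), 0.32 ± 0.49 for Card9, -0.11 ± 0.24 for Pigr and 0.95 ± 0.51 for Igha, with adjusted p from 0.346 (Clec7a) to 0.840 (Pigr). Il17a had 1 count in the 8 libraries together, Il22 had 0, Reg3b 19 and S100a8 6, and these 4 were not tested; a difference in Il22 was not detectable at this depth, where 0 counts allow up to 0.152 to 0.185 CPM in a library. As groups, type 17 immunity (median -0.38, adjusted p = 0.599), fungal recognition (0.01, adjusted p = 0.885) and antimicrobial defence (0.12, adjusted p = 0.487) did not pass. Neither did interferon-gamma (0.09, adjusted p = 0.496) or type I interferon (-0.18, adjusted p = 0.885). The type 17 list had 8 of its 20 genes tested, without Il17a and Il22, and so leaves those cytokines undecided. Its score also ran against that of smooth muscle within groups (r = -0.941).

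With C. tropicalis, Per2 rose from 35.2 ± 5.22 to 213 ± 64.7 CPM (SD, n = 3 and 2; 6.06-fold, log2 2.599 ± 0.22, adjusted p = 0.0134). Hspa8, the constitutive HSP70 chaperone, rose from 924 ± 130 to 3209 ± 422 CPM (3.47-fold, log2 1.80 ± 0.21, adjusted p = 0.0409). Fmo2, a flavin-containing monooxygenase, rose from 21.9 ± 3.99 to 70.6 ± 13.9 CPM (3.23-fold, log2 1.69 ± 0.18, adjusted p = 0.0389), and Rbm14 from 19.2 ± 1.19 to 51.0 ± 2.86 CPM (2.65-fold, log2 1.41 ± 0.15, adjusted p = 0.0372). Dhrs3, which reduces retinaldehyde and so limits retinoic acid, fell from 50.4 ± 2.19 to 21.6 ± 1.61 CPM (0.429-fold, log2 -1.22 ± 0.14, adjusted p = 0.0409). Both C. tropicalis libraries lay beyond all 3 controls for each of the 5, which the rule for naming them requires. Over all tested genes 32.5% did so, where chance gives 20%.

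These 5 genes, 4 higher and 1 lower, were all that passed with edgeR, beside 2477 genes at an unadjusted p under 0.05 (805 by chance) and 10 at an adjusted p under 0.1. DESeq2 gave 393, the fit with no filter on low counts 71, the correction for GC content 2 (Hspa8, Fmo2 and Dhrs3 were lost), and the replicate block, the smooth muscle covariate and the fit of only these 2 groups 0 each. Tested against a minimum fold of 1.5, Per2 alone passed, and with limma-voom Dhrs3 missed (adjusted p = 0.0582). With the muscle covariate the log2 fold changes were 2.54 ± 0.31 for Per2, 1.83 ± 0.29 for Hspa8, 1.47 ± 0.23 for Fmo2, 1.55 ± 0.20 for Rbm14 and -1.13 ± 0.19 for Dhrs3 (adjusted p from 0.0694 to 0.117), with standard errors 1.22 to 1.41 times those without it. Without 1 library the count was 0 (control 1), 0 (control 2), 192 (control 3), 1 (C. albicans 2), 1 (C. albicans 3), 0 (C. tropicalis 1) and 1 (C. tropicalis 2), and Dhrs3 also missed without C. albicans 1 (adjusted p = 0.0860). Hspa8 (ENSMUSG00000015656) lies on chromosome 9 from 40800984 to 40810087, Fmo2 (ENSMUSG00000040170) on chromosome 1 from 162874317 to 162898726 and Dhrs3 (ENSMUSG00000066026) on chromosome 4 from 144892827 to 144928209.

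The unfolded protein response list was higher with C. tropicalis (median 0.33, 25 of 26 members above control, adjusted p = 2.27e-07; 11 adjusted over the list alone, 0 over all genes), with Hspa5 at 1.17 ± 0.19 (adjusted p = 0.104) and Pdia4, a folding enzyme of the same compartment, at 0.84 ± 0.17 (adjusted p = 0.151). All 32 cell cycle genes lay above control (median 0.50, adjusted p = 2.53e-07), with Ccne1 at 0.95 ± 0.24 (adjusted p = 0.190) and Mcm3 at 0.76 ± 0.20 (adjusted p = 0.206); none passed, over all genes or adjusted over the list alone. The cell cycle score was 0.46, -0.14 and -0.42 in control 1, 2 and 3. It was 0.63 and 0.42 in C. tropicalis 1 and 2, so control 1 lay above C. tropicalis 2. All 22 smooth muscle genes lay below control (median -0.99, adjusted p = 2.70e-07; 5 adjusted over the list alone, 0 over all genes), with Cnn1 at 421 ± 78.2 CPM against 1326 ± 488 (log2 -1.65 ± 0.48, adjusted p = 0.220) and Kcnmb1 at -1.20 ± 0.30 (adjusted p = 0.184). Enteric neuron and glia genes were lower in 22 of 23 cases (median -0.83, adjusted p = 8.78e-07; 0 passed either way), with Ret at -0.88 ± 0.28 (adjusted p = 0.250) and Erbb3 at -0.83 ± 0.27 (adjusted p = 0.254). Fatty acid oxidation genes were lower in 26 of 29 cases (median -0.25, adjusted p = 0.000256; 3 adjusted over the list alone, 0 over all genes), with Angptl4 at -2.57 ± 0.49 (adjusted p = 0.135) and the carnitine carrier Slc25a20 at -0.71 ± 0.17 (adjusted p = 0.169). All 14 adipocyte genes lay below control (median -1.16, adjusted p = 0.000959; 3 adjusted over the list alone, 0 over all genes), with Lpl at -1.70 ± 0.47 (adjusted p = 0.213) and Adrb3 at -1.20 ± 0.31 (adjusted p = 0.201). Each of these 6 lists had adjusted p = 0.676 with an estimated correlation and kept its call without each library in turn, at no more than 0.0411, though the cell cycle median was 0.79 without control 1 and 0.30 without control 3, and without C. tropicalis 1 the nerve median was -0.45 and that of fatty acid oxidation -0.17. The nerve call, however, ended with the smooth muscle score as a covariate (median -0.0387, adjusted p = 0.722).

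The clock list was higher with C. tropicalis as well (median 0.50, 11 of 19 above control, adjusted p = 0.0101; adjusted p = 0.676 with an estimated correlation), with 1 gene past the threshold over all genes and 12 adjusted over the list alone, 9 higher and 3 lower; it missed without C. tropicalis 1 (median 0.31, adjusted p = 0.0524) and had a median of 0.31 without control 3 (adjusted p = 0.0486). Immediate early and heat shock genes, with a median of 0.06, did not pass as a list (adjusted p = 0.0926). Fibroblast genes (median -0.38, 25 of 26 lower, adjusted p = 0.000342; adjusted p = 0.711 with an estimated correlation; 1 adjusted over the list alone) included Fbn1 at -1.14 ± 0.22 (adjusted p = 0.135) and Pdgfra at -0.78 ± 0.25 (adjusted p = 0.243). Tuft cell genes (median -0.78, 18 of 20 lower, adjusted p = 0.00305; adjusted p = 0.676 with an estimated correlation; 0 adjusted over the list alone) included Kctd12 at -0.91 ± 0.26 (adjusted p = 0.217). Without C. tropicalis 2 both of these calls ended (adjusted p = 0.0638 each). Endothelial genes were lower (median -0.24, adjusted p = 0.0205; adjusted p = 0.711 with an estimated correlation; 0 adjusted over the list alone), with Kdr at -0.67 ± 0.18 (adjusted p = 0.206) and Pecam1 at -0.46 ± 0.17 (adjusted p = 0.267), and missed without control 3 (adjusted p = 0.179) or C. tropicalis 2 (0.236). Without control 3 the fibroblast median was -0.24 and the endothelial one -0.15, and without C. tropicalis 2 the fibroblast median was -0.25. All 3 calls ended with the smooth muscle score as a covariate, with medians of -0.12 for fibroblast (adjusted p = 0.184), -0.36 for tuft cell (0.423) and -0.21 for endothelial genes (0.0956). No member of these 3 lists passed over all genes.

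Squamous epithelium genes were higher in 5 of 6 cases (median 0.60, adjusted p = 0.0205; adjusted p = 0.676 with an estimated correlation; 2 adjusted over the list alone, 0 over all genes), with Krt14 at 1.92 ± 0.40 (adjusted p = 0.151) and Sfn at 1.17 ± 0.31 (adjusted p = 0.206); the call ended without C. tropicalis 1 (adjusted p = 0.05002) or C. tropicalis 2 (0.198). Hypoxia and glycolysis genes were higher in 22 of 31 cases (median 0.25, adjusted p = 0.0284; adjusted p = 0.786 with an estimated correlation; 2 higher and 1 lower adjusted over the list alone, 0 over all genes), with Hif1a at 0.97 ± 0.12 (adjusted p = 0.0645) and P4ha1 at 0.95 ± 0.19 (adjusted p = 0.137), and missed without control 1 (adjusted p = 0.0914), control 3 (0.143) or C. tropicalis 1 (0.0737). Markers of proximal colon were lower in 10 of 14 cases (median -0.64, adjusted p = 0.0374; adjusted p = 0.676 with an estimated correlation; 3 adjusted over the list alone, 0 over all genes). Among them Hao2 had -1.12 ± 0.20 (adjusted p = 0.120). That list missed without control 1 (adjusted p = 0.0575), control 2 (0.0926), C. albicans 3 (0.0513), C. tropicalis 1 (0.0711) or C. tropicalis 2 (0.0562). The squamous median was 0.37 without C. tropicalis 1 and 0.21 without C. tropicalis 2, and the hypoxia median 0.41 without control 2. The smooth muscle score as a covariate ended the hypoxia call (median 0.20, adjusted p = 0.109) and put the proximal median at -0.20 (adjusted p = 0.0379). In total 13 of 40 lists passed by camera, 5 higher and 8 lower, 0 by fry (smallest adjusted p = 0.0949) and 0 with an estimated correlation, where 1 had an unadjusted p under 0.05.

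Defence readouts did not pass with C. tropicalis either. Log2 fold changes were 0.57 ± 0.30 for Duox2, -0.21 ± 0.30 for Muc2, -2.80 ± 1.70 for Retnlb, -1.26 ± 0.87 for Reg3g and 0.43 ± 0.42 for Lcn2. They were -0.89 ± 0.38 for Clec7a, 0.32 ± 0.55 for Card9, -0.12 ± 0.27 for Pigr and 0.47 ± 0.56 for Igha. Adjusted p ran from 0.315 (Clec7a) to 0.859 (Pigr). With C. tropicalis, Reg3g and Retnlb lay at or close to the 0.152 to 0.185 CPM that a count of 0 allows, so the size of their falls is uncertain. Type 17 immunity, with 8 of its 20 genes tested (median 0.03, adjusted p = 0.235), and fungal recognition (0.20, adjusted p = 0.327) did not pass as lists. Neither did interferon-gamma (0.09, adjusted p = 0.327) or type I interferon (-0.37, adjusted p = 0.327). Antimicrobial defence had a median of -0.12 and a mean of -0.38 while camera ranked it upward (adjusted p = 0.930).

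Between the species, the differences with the smallest p were mostly lower values with C. tropicalis, and none passed. Klhl29 stood at 3.41 ± 0.0993 CPM with C. tropicalis and 18.0 ± 5.34 with C. albicans (SD, n = 2 and 3; log2 -2.39 ± 0.29), and Inhbb, a subunit of activins and inhibins, at 1.08 ± 0.167 and 6.56 ± 1.30 (-2.59 ± 0.33). The interleukin 4 and 13 receptor gene Il4ra had -1.02 ± 0.13, the guidance cue Ntn1 -0.99 ± 0.13, Jph3 -2.35 ± 0.33, Igdcc4 -1.24 ± 0.18 and Basp1 -1.46 ± 0.22. Higher with C. tropicalis were S100a14 at 143 ± 5.65 CPM against 42.1 ± 3.49 (1.76 ± 0.26), Fmo2 (1.38 ± 0.18) and Anxa8 (1.24 ± 0.18). Each of these 10 had adjusted p = 0.0646, the smallest in the contrast. By the rule for naming them, the libraries of the species did not overlap for any of the 10. Over all genes 45.9% did not overlap, where chance gives 20%.

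The edgeR test called 0 genes between the species, beside 3744 at an unadjusted p under 0.05 (805 by chance) and 1481 at an adjusted p under 0.1, 343 higher and 1138 lower with C. tropicalis; limma-voom called 0 and DESeq2 1737. The count was 858 with only the 2 groups and 1127 with no filter, and it rose to 925 without control 1, 897 without control 3 and 1315 without C. albicans 1. With the smooth muscle score as a covariate, chosen after the data had been seen, 0 genes were called and 1008 had an unadjusted p under 0.05. That score did not overlap between the species, so that fit does not separate tissue share from a species difference that runs with it. Among the defence readouts, Duox2 was at 80.1 ± 7.28 CPM with C. tropicalis (log2 -1.04 ± 0.31 against C. albicans, adjusted p = 0.0960) and Muc2 at 2631 ± 291 (-0.96 ± 0.31, adjusted p = 0.111). Retnlb was at 0.312 ± 0.360 (-5.59 ± 1.73, adjusted p = 0.104) and Reg3g at 0.170 ± 0.0795 (-2.46 ± 0.83, adjusted p = 0.123). Reg3g thus lay within the 0.152 to 0.185 CPM that a count of 0 allows. Retnlb lay close to it, with an SD above its mean, so the size of both falls is uncertain. Lcn2 (0.24 ± 0.42), Clec7a (-0.20 ± 0.38), Card9 (0.00 ± 0.55), Pigr (-0.01 ± 0.27) and Igha (-0.48 ± 0.58) differed by less than their errors. Type 17 immunity, with 8 of its 20 genes tested (adjusted p = 0.208), and fungal recognition (0.627) did not pass as lists. Neither did antimicrobial defence (0.583), interferon-gamma (0.868) or type I interferon (0.420).

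Between the species, smooth muscle and nerve genes had the smallest camera p of the lists; by size of the median the nerve list came after the adipocyte and tuft cell lists. All 22 smooth muscle genes were lower with C. tropicalis (median -1.64, adjusted p = 7.55e-11; 21 adjusted over the list alone), with Actg2 at 702 ± 133 CPM against 3931 ± 2307 (log2 -2.49 ± 0.48, adjusted p = 0.0646) and Kcnmb1 at -1.52 ± 0.30 (adjusted p = 0.0646). All 23 genes of enteric neurons and glia were lower (median -1.36, adjusted p = 2.48e-10; 18 adjusted over the list alone), with Ret at -1.63 ± 0.29 (adjusted p = 0.0646) and Foxd3 at -1.66 ± 0.34 (adjusted p = 0.0646). All 32 cell cycle genes were higher (median 0.77, adjusted p = 3.30e-10; 13 adjusted over the list alone), among them Rrm1 (1.07 ± 0.20, adjusted p = 0.0646) and Rrm2 (1.14 ± 0.25, adjusted p = 0.0658), the subunits of ribonucleotide reductase. Fibroblast genes were lower in 24 of 26 cases (median -0.53, adjusted p = 2.28e-06; 13 adjusted over the list alone), with Fn1 at -1.37 ± 0.25 (adjusted p = 0.0646) and Fbn1 at -0.98 ± 0.22 (adjusted p = 0.0669). Tuft cell genes were lower in 18 of 20 cases (median -1.43, adjusted p = 1.43e-05; 9 lower and 1 higher adjusted over the list alone), with Kctd12 at -1.48 ± 0.26 (adjusted p = 0.0646) and Hpgds higher at 1.14 ± 0.25 (adjusted p = 0.0665). Endothelial genes were lower in 18 of 20 cases (median -0.50, adjusted p = 0.000263; 11 adjusted over the list alone), with Kdr at -0.84 ± 0.18 (adjusted p = 0.0658) and Vwf at -0.76 ± 0.19 (adjusted p = 0.0700). Each of these 6 lists had adjusted p = 0.613 with an estimated correlation, 0 members past the threshold over all genes, and kept its call without each library in turn. With the smooth muscle score as a covariate the nerve (median -0.12, adjusted p = 0.520) and tuft cell calls (-0.50, adjusted p = 0.0908) ended, and the fibroblast median was -0.33 (adjusted p = 0.0450).

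Adipocyte genes were lower in 13 of 14 cases (median -1.51, adjusted p = 0.00157; adjusted p = 0.642 with an estimated correlation; 4 adjusted over the list alone), with Lpl at -1.95 ± 0.48 (adjusted p = 0.0694) and the lipid droplet gene Cidec at -3.05 ± 0.78 (adjusted p = 0.0740), and the call held without each library. Immediate early and heat shock genes were lower in 20 of 24 cases (median -0.35, adjusted p = 0.00181; adjusted p = 0.613 with an estimated correlation; 6 adjusted over the list alone), with Fos at -1.11 ± 0.18 (adjusted p = 0.0646) and the small heat shock gene Hspb1 at -2.08 ± 0.35 (adjusted p = 0.0646); without C. tropicalis 2 the list missed (adjusted p = 0.101), and without C. tropicalis 1 its median was -0.56. B cell genes were higher in 19 of 20 cases (median 0.89, adjusted p = 0.0477; adjusted p = 0.856 with an estimated correlation; 0 adjusted over the list alone), with Cxcl13, which draws B cells into follicles, at 1.14 ± 0.59 (adjusted p = 0.287). That call ended without control 3 (adjusted p = 0.0635), C. albicans 2 (0.313, median 0.40), C. tropicalis 1 (0.0609) or C. tropicalis 2 (0.0817, median 0.57) and with the stricter filter on low counts (0.0777), and with the smooth muscle score as a covariate the list passed in the other direction (median -2.08, adjusted p = 1.56e-07). That covariate put the adipocyte median at -0.97 and the heat shock list at -0.64, both still past the threshold. In these 3 lists 0 members passed over all genes. The clock list did not differ as a whole (median -0.18, adjusted p = 0.544), with 4 genes higher and 6 lower adjusted over the list alone. By camera 9 of 40 lists passed, 2 higher and 7 lower with C. tropicalis, against 0 by fry and 0 with an estimated correlation, where 0 had an unadjusted p under 0.05.

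**Figure D3:**
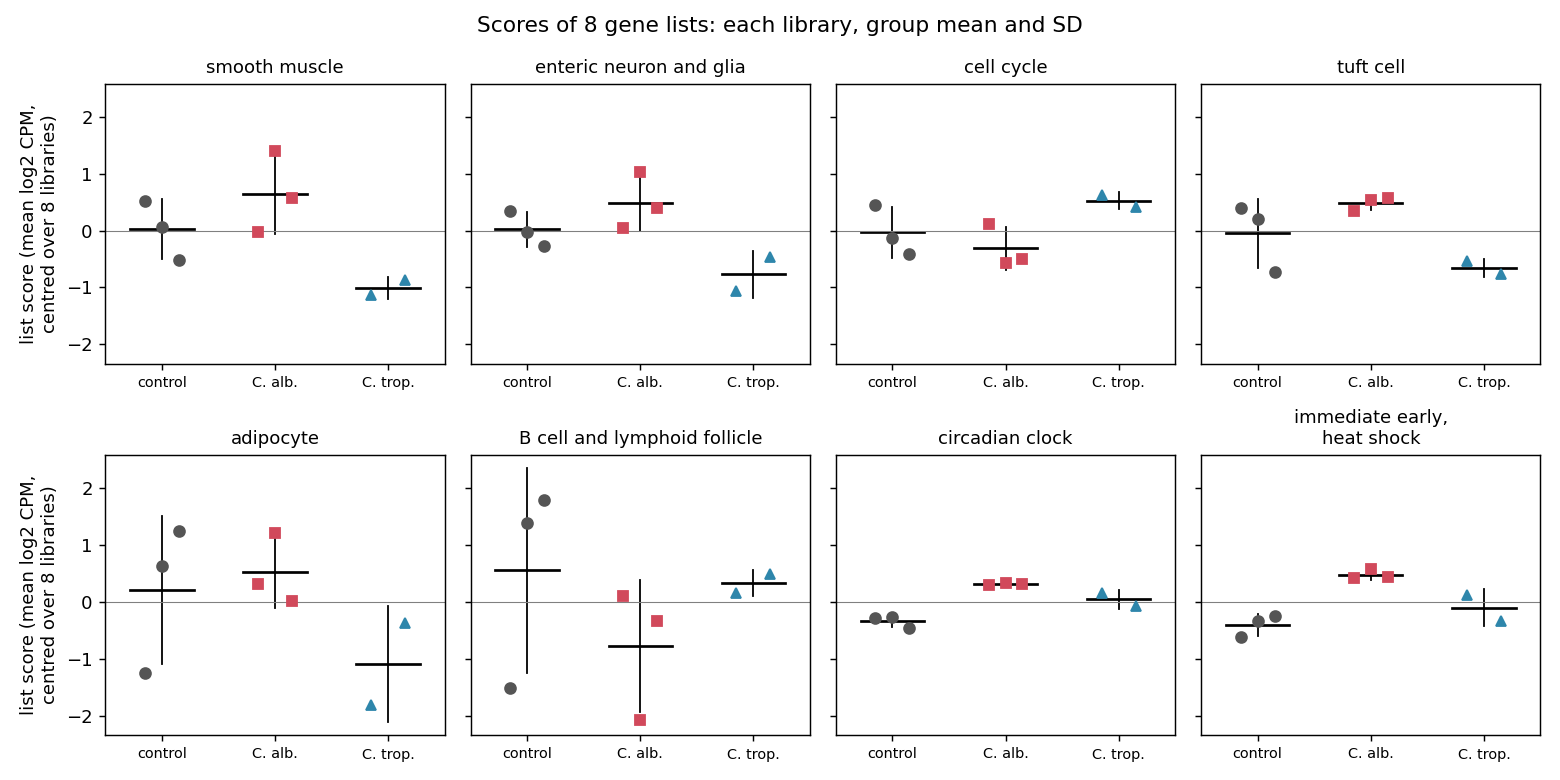
Score of 8 gene lists (y axis, mean log2 CPM of the members, centred over the 8 libraries) in each library, with the group mean (bar) and SD (line). The C. tropicalis libraries lie at -1.14 and -0.87 for smooth muscle, below all others, while the B cell scores of the controls run from -1.52 to 1.79.

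Per2 and Rbm14 passed as higher with both species, and for lower genes the shared count was 0. Neither was shared with only the 2 groups, the replicate block or the smooth muscle covariate, nor without control 1, control 2, control 3, C. albicans 3 or C. tropicalis 1; Per2 alone was with the GC correction, a minimum fold of 1.5, and without C. albicans 2 or C. tropicalis 2. The shared counts of higher and lower genes were 67 and 13 with DESeq2, 20 and 2 with no filter, 4 and 0 without C. albicans 1, and 1 and 1, other genes, without control 3. Lists of these sizes with no library in common would share 0.00149 higher genes by chance, but the contrasts share their controls, so that is no chance level for them and part of the overlap may come from the controls. All 10 genes called in either contrast had the same sign in both, among them Arntl (-1.69 and -0.91), Hsph1 (2.48 and 2.20) and Hspa8 (1.22 and 1.80), and at an adjusted p under 0.1 Hspa8 and Hsph1 were shared too, making 4. Shared controls alone make fold changes alike. Across all tested genes, which are not independent, the log2 fold changes correlated at r = 0.0378. In 100 simulated data sets without any response the mean was 0.439 and the highest 0.475. The simulations drew each gene independently, while the real libraries share a main axis with 48.7% of the variance. Their narrow range is thus no chance level for these data, and no conclusion is drawn from the observed r lying below it. The covariance was 0.0129 against 0.0733 in the simulations, a difference of -0.0603, and 55.7% of genes had the same sign against 64.7%. With the 3 controls split 1 and 2 between the contrasts, a choice made after the data had been seen, r ran from -0.456 to 0.0562 over the 6 ways (mean -0.187) and the covariance from -0.302 to 0.0183 (mean -0.115); the 10 genes, which had been picked with all the controls, had the same sign in both contrasts in each of the 6. With no filter on low counts r was 0.381. Without 1 library r lay between -0.0608 (without C. albicans 1) and 0.179 (without control 3), with 0.149 without control 1, 0.0893 without control 2, 0.163 without C. albicans 2, 0.00930 without C. tropicalis 1 and 0.0687 without C. tropicalis 2.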

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

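The tests of the muscle share, of another part of the colon and of dilution of cell cycle genes were chosen after these differences had been seen. Each list in this part stands out because a camera test of the difference between the species passed its threshold; with an estimated correlation none of the 9 did (smallest adjusted p = 0.613), and 0 single genes passed with edgeR (3744 at an unadjusted p under 0.05; DESeq2 1737). With the smooth muscle score as a covariate in edgeR, 1008 genes had an unadjusted p under 0.05, where chance gives 805.

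With C. tropicalis against C. albicans, the median log2 fold change was -1.64 for smooth muscle genes and -1.36 for genes of enteric neurons and glia. Cell cycle genes had 0.77. A smaller share of the muscle layer in the C. tropicalis pieces may account for the muscle and nerve difference, since the 2 scores moved together within groups. Over 8 libraries r was 0.942 and rho 0.976 (exact two-sided permutation p = 0.0139 for each, the smallest its 72 rearrangements can give). Without C. albicans 2 and C. tropicalis 1 r was 0.985. Another part of the colon could move both scores too, so r does not tell these apart. Within groups the muscle score rose with proximal markers (r = 0.644) and fell with distal ones (-0.702). It also rose with goblet (0.640), tuft (0.627), enteroendocrine (0.706) and colonocyte scores (0.224), which a larger muscle share alone would lower. With crypt stem scores it fell (-0.661). Dilution by the same share is argued against for the cell cycle genes, since their median lay 0.85 above that of absorptive colonocytes (-0.07, bootstrap interval over genes -0.40 to 0.20). It stayed at 0.77 with the smooth muscle score as a covariate. That score did not overlap between the species, so this fit rests on the slope within groups and cannot settle the question. Other changes of tissue make-up, such as the share of cycling cells, were not tested. Pieces from another part of the colon stay open, with a median of 0.13 for distal markers (interval -1.21 to 2.52) and -0.57 for proximal ones, and so does a difference between the species themselves, which could not be separated from how the pieces were taken.

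Fibroblast and extracellular matrix genes had a median of -0.53 between the species. Tuft cell genes had -1.43. For endothelial genes the median was -0.50. Adipocyte genes lay at -1.51, with scores of -1.81 and -0.37 in the C. tropicalis libraries and from -1.25 to 1.25 in the controls. With the smooth muscle score as a covariate the tuft cell call ended (median -0.50, adjusted p = 0.0908 by camera). The fibroblast, endothelial and adipocyte medians were then -0.33, -0.42 and -0.97, still past the threshold. Immediate early and heat shock genes differed by -0.35, a call that ended without C. tropicalis 2 (adjusted p = 0.101). B cell and follicle genes differed by 0.89, a call that ended without control 3 (adjusted p = 0.0635), C. albicans 2 (0.313), C. tropicalis 1 (0.0609) or C. tropicalis 2 (0.0817), while with the smooth muscle score as a covariate the list passed in the other direction (median -2.08, adjusted p = 1.56e-07).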

How the results depend on the processing

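The smooth muscle covariate, the correction for GC content and the split of the controls were chosen after the data had been seen. The cause of each change was not tested, except that more genes pass at a looser threshold. The fit with no filter had more genes (26975) and a prior of 10.7 degrees of freedom against 4.05, which were not varied apart. The replicate numbers were not taken to pair the libraries: deviations of libraries of the same number correlated across genes at -0.392, -0.0795 and -0.128 (control and C. albicans), -0.0188 and 0.0290 (control and C. tropicalis) and 0.156 and 0.147 (C. albicans and C. tropicalis), against -0.295 to 0.362 for different numbers.

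For C. albicans against control, 7 genes passed with DESeq2 size factors, upper-quartile factors, the stricter filter and limma-voom, 8 with only the 2 groups and 10 with the muscle covariate, 6 of the 7 each time (Rbm14 missed, adjusted p = 0.0754 and 0.0525). The count was 461 with DESeq2, 119 with no filter, 0 with the replicate block, 4 with a minimum fold of 1.5, 43 at an adjusted p under 0.1 and 4 with the GC correction; it ran from 0 (without C. albicans 3) to 254 (without C. albicans 1), with 1 without control 1, 1 without control 2 and 2 without control 3. With the block, which leaves 3 residual degrees of freedom against 5, the log2 fold changes of the 7 were 0.996 to 1.020 times their values without it. After the GC correction C2cd4a went from 3.06 to 2.25 (adjusted p = 0.0763), Per1 from 1.31 to 1.051 and Rbm14 from 1.1801 to 1.049 (adjusted p = 0.0516 each); fold changes followed GC content at a Spearman rho of 0.329 before and 0.0209 after. Of the 10 splits of these 6 libraries into 3 and 3, the real one gave 7 genes and 3, itself included, gave as many or more; 10 are too few for a share under 0.05. The highest other, control 1, C. albicans 2 and C. albicans 3 against the rest, gave 373, which points to a structure of the libraries other than the groups; their smooth muscle scores were 0.53, 1.39 and 0.58 against 0.07, -0.52 and -0.03.

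For C. tropicalis against control, 5 genes passed with both other scalings and the stricter filter and 4 with limma-voom, where Dhrs3 missed (adjusted p = 0.0582). The count was 393 with DESeq2, 71 with no filter, 0 with only the 2 groups, 0 with the replicate block, 1 with a minimum fold of 1.5, 10 at an adjusted p under 0.1, 0 with the muscle covariate and 2 with the GC correction; it ran from 0 (without control 1, control 2 or C. tropicalis 1) to 192 (without control 3), with 1 without C. albicans 2, C. albicans 3 or C. tropicalis 2. The log2 fold changes of the 5 were 0.994 to 1.059 times their values with the block and 0.999 to 1.001 times with only the 2 groups. After the GC correction Hspa8 went from 1.80 to 1.80, Fmo2 from 1.69 to 1.68 and Dhrs3 from -1.22 to -1.23 (adjusted p = 0.0552 each). Between the species the count was 0 with both other scalings, the stricter filter, the block, a minimum fold of 1.5, limma-voom and the added alternatives, 1737 with DESeq2, 1127 with no filter, 858 with only the 2 groups and 1481 at an adjusted p under 0.1; it ran from 0 to 1315 (without C. albicans 1), with 925 without control 1 and 897 without control 3.

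Lists past the threshold numbered 14, 13 and 9 in the 3 contrasts, 0, 0 and 0 with an estimated correlation, 2, 0 and 0 by fry, 12, 14 and 10 with the block, which ended the calls of fibroblast and endothelial genes with C. albicans (adjusted p = 0.0715 and 0.0732) and of endothelial genes and proximal markers with C. tropicalis (0.0839 and 0.0569), and 13, 13 and 18 with the muscle covariate, which is circular for smooth muscle itself. That covariate turned the direction of MHC class II (median -0.18) and B cells (-0.46) with C. albicans, where the test turned and the median did not, and of B cells between the species (-2.08), which passed the other way (adjusted p = 1.56e-07). It also ended the calls of nerve, fibroblast, endothelial and tuft cell genes with C. albicans (adjusted p = 0.663, 0.450, 0.121 and 0.189) and with C. tropicalis (0.722, 0.184, 0.0956 and 0.423), of hypoxia genes with C. tropicalis (0.109), and of nerve and tuft cell genes between the species (0.520 and 0.0908). The correlation of the 2 contrasts, 0.0378, turned to -0.0251 with the stricter filter, -0.0692 with the block, -0.0453 with limma-voom and -0.187 with the controls split between the contrasts, was 0.381 with no filter, and ran from -0.0608 (without C. albicans 1) to 0.179 (without control 3). The 2 thresholds give no value for it.

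No gene past the threshold changed sign. Defence readouts and the B cell attractant Cxcl13, none of which had passed, turned with the muscle covariate: with C. albicans Pigr (0.12); with C. tropicalis Reg3g (0.29), Card9 (-0.56), Muc2 (0.44), Retnlb (1.19) and Igha (-0.40); between the species Cxcl13 (-0.79), Reg3g (0.21), Lcn2 (-0.10), Muc2 (0.025) and Retnlb (0.071). Between the species Card9 turned with no filter (0.00090), the block (0.26), limma-voom (0.049) and the GC correction (0.12), and Pigr with limma-voom (0.025). With libraries left out, values ran from -0.025 to 0.65 for Lcn2 and -0.29 to 0.14 for Pigr with C. albicans; from -0.40 to 0.11 for Muc2, -0.27 to 0.11 for Pigr and -0.057 to 0.86 for Igha with C. tropicalis; and from -0.44 to 0.0045 for Clec7a, -0.20 to 0.22 for Card9, -0.18 to 0.17 for Pigr and -1.01 to 0.10 for Igha between the species. For named genes, called or not, 1846 values kept direction and side of the threshold, 242 newly passed and 28 turned. Gene calls ended 93 times, each kept in 7 (Dhrs3) to 18 (Arntl) of 20 alternatives. The 36 list calls, followed because they had passed, held 328 times, ended 137 and turned 3 over 13 alternatives each. Other lists passed 77 times, with the muscle covariate 6, 6 and 12 in the 3 contrasts. Depth limits Il17a, Il22, Reg3b and S100a8, with 1, 0, 19 and 6 counts in all.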

Other observations

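The tests of the muscle share and of collection time for the clock genes and of slow handling for the heat shock genes were chosen after the results had been seen; that of the temperature rhythm was chosen after the heat shock genes had been seen and before Cirbp and Rbm3 had been.

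Interferon-stimulated genes were highest in control 1. The type I interferon score was 1.1796 there, -0.47 in control 2 and -0.56 in control 3, 0.54, -0.23 and -0.02 in the C. albicans libraries and 0.10 and -0.54 in the C. tropicalis libraries. Among genes chosen after their values were seen, Ifit1 had 26.8 CPM in control 1 and 0.753 to 6.91 in the other 7 libraries, Isg15 had 21.5 against 1.81 to 8.04, and Oasl2 had 102 against 9.03 to 62.5. Hspa1a, the inducible HSP70 gene, also chosen afterwards, stood at 254, 377 and 168 CPM with C. albicans against 23.9, 25.4 and 28.6 in controls (log2 3.36 ± 0.47, adjusted p = 0.0711 with edgeR). Its reads cannot be told from those of its near-identical neighbour Hspa1b (log2 3.32 ± 0.47, adjusted p = 0.0711).

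With C. albicans, clock genes differed from control in both directions, with a median log2 fold change of 1.32 over 10 genes of the arm of Per, Dbp and their co-regulated genes and -0.81 over Arntl, Clock, Npas2 and Nfil3. With C. tropicalis, where 1 clock gene passed over all genes (Per2), the medians were 0.65 and -0.81, and Dbp (-0.11), Hlf (-0.0094), Nr1d1 (-1.001), Bhlhe41 (-0.44) and Clock (0.22) ran against their arm. A different share of muscle in the pieces is argued against, since with the smooth muscle score as a covariate the medians lay 1.94 apart with C. albicans (bootstrap interval over genes 1.02 to 2.95; 2.12 without it), where Arntl, Per1, Per2 and Ciart still passed, and 1.75 apart with C. tropicalis (0.64 to 2.35; 1.45 without it), where Per2 did not (2.54 ± 0.31, against 2.599 ± 0.22); other changes of tissue make-up were not tested. These intervals treat co-regulated genes as independent and leave out the spread between libraries. With C. tropicalis, whose smooth muscle scores lay below those of all controls, the fit rests on the slope within groups. Later collection of the C. tropicalis mice may add to the difference between the species, in which no clock gene passed with edgeR, since those with a later usual peak had higher fold changes (Spearman rho = 0.759, permutation p = 0.0024, two-sided; Pearson r = 0.767, permutation p = 0.0013; 15 genes, which are not independent). The labels give no hour of collection, so that cannot be told apart from an effect of colonization on the clock, and collection of the colonized mice at another time than the controls stays open, untested.

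The list of immediate early and heat shock genes was higher with C. albicans by camera (adjusted p = 0.476 with an estimated correlation) but did not pass with C. tropicalis (adjusted p = 0.0926), and of its 6 heat shock genes, which were not tested as a set, Hsph1 passed with C. albicans and Hspa8 with C. tropicalis. The median of the 6 was 1.85 with C. albicans and 1.46 with C. tropicalis, where Hspb1 ran the other way (-1.46 ± 0.34). Slow handling of the tissue, which would raise immediate early genes too, is argued against with C. tropicalis, where the median of 18 such genes was -0.0424 (bootstrap interval over genes -0.21 to 0.20), but stays open with C. albicans, where it was 0.40 (0.30 to 0.84). A daily temperature rhythm sampled at another time may account for these values: Cirbp and Rbm3, transcripts induced by cold that run opposite to heat shock genes over the day, had a mean of -0.40 with C. albicans and -0.67 with C. tropicalis, most of it from Cirbp (-0.67 ± 0.19 and -1.14 ± 0.22), with Rbm3 at -0.13 ± 0.15 and -0.20 ± 0.17. The rhythm and a response to the fungi cannot be told apart here, as each colonized group may have been sampled at its own time.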
